A study of Mus musculus with 6 samples.

How the data were processed

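Messenger RNA was sequenced from mouse bone marrow-derived dendritic cells (BMDC, dendritic cells grown out of marrow in culture) that were labelled either as given NanoCa or as given no treatment (Mock). NanoCa is the calcium-containing lipid nanoparticle of the series title, and per the labels' protocols it was used at 100 μM. That protocol stands on the Mock samples too, and their descriptions name a column with both Mock and NanoCa in it, so it is not settled here whether Mock cells were given a particle. Their treatment label gives no treatment, and the treatment label was followed, so every difference rests on it. The labels give 3 samples per group, 1 shared batch date for all 6, and female mice. RNA was extracted with a phenol-based reagent and made into libraries with a SMARTER mRNA kit, per the labels' protocols. Time of exposure, aligner, read counter and their versions are not given in the sources used here. The genome build is GRCm39, per the submitters' processing notes.

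The deposited table holds FPKM values (reads scaled by the length of the gene and by the total reads of the library) for 55487 genes, as the authors computed them. Of these, 31558 were listed at 0 in all 6 columns. FPKM is not a count, so no count model was the main test. Gene symbols were taken from the table, and 99.4% of its identifiers matched the GENCODE annotation used here. That annotation is of GRCm38, so it served only for transcript lengths and for the chromosome of a gene, and no coordinates are given.

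In both groups the column of replicate 3 equalled 1 constant times the mean of replicates 1 and 2 for every gene with a value. The constant was 1.0011 over 21557 genes in NanoCa and 1.001876 over 22162 genes in Mock, and the ratio varied by less than 1e-06 between genes. No gene had a value in replicate 3 alone. Both columns were therefore treated as means, which carry no spread of their own, and every test used the 4 remaining libraries, 2 per group. This departs from the planned comparison of 3 against 3, which was run as an alternative. The labels do not say that replicates came from separate animals or cultures. Between replicates 1 and 2, genes with 20 to 100 reads over both libraries varied close to counting noise (mean chi-square per gene 1.06 in NanoCa and 1.18 in Mock), while genes with 100 to 1000 reads (1.34 and 1.81) and with 1000 reads or more varied above it. The p-values measure only the spread between these libraries, which may be technical.

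The depth was read from the values. In each library, FPKM times gene length rose in steps of 1 read, and whole reads (tolerance 1e-06) came out for 23926 of 23929 genes with a value in those libraries. The library totals behind the FPKM were 23991472 and 22793565 reads in NanoCa replicates 1 and 2, and 31131990 and 26975437 in Mock replicates 1 and 2. The recovered reads summed to 99.99% of those totals. The recovered length was the shortest that gave whole reads. Where an annotated transcript length of the gene was a multiple of it, the shortest such length was taken. For 99.1% of tested genes the length then equalled that of an annotated transcript, a share that this step can raise by construction. In simulated tables the same procedure returned the exact reads of 99.9% of 3787 genes and 4 of 4 library totals. Those tables were built from the recovered lengths, so they do not test the lengths. One read in a gene of 1 kilobase was worth 0.0321 to 0.0439 FPKM. Intervals (95%, exact) cover counting error only.

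Genes with a mean FPKM of at least 1 over all libraries (11116 genes) were tested with limma 3.58.1 in R 4.3.3, on log2(FPKM + 1), with lmFit and eBayes with a trend. Tests were two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. All log2 fold changes are NanoCa minus Mock on the log2(FPKM + 1) scale, which understates the change of low genes. On simulated reads at the same depth for the same comparison, with a dispersion of 0.002 and 11115 genes tested, the test recovered 28% of 50 genes changed 1.25-fold, 85.7% of 49 changed 1.5-fold, 98% of 50 changed 2-fold and 97.8% of 45 changed 4-fold. It called 12 of 10885 unchanged genes, 6.09% of its calls. Most genes were left unchanged there and no shift from scaling to total reads was simulated. These rates therefore need not hold for the real comparison. A simulated fall of the cell cycle list was found (camera adjusted p = 3.6e-109), with 0 other lists called. The simulated genes were drawn independently of each other, so this does not measure false list calls where genes vary together.

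Before the data were examined, 33 gene lists (processes and cell type markers), the alternatives and the rule for naming genes were fixed. The lists were tested with camera (limma) at a preset inter-gene correlation of 0.01, adjusted over the 30 lists with at least 3 tested members, with an estimated correlation and with fry beside it. With 2 libraries per group, camera with an estimated correlation has little power. A call lost there does not decide whether correlation between genes accounts for it, and the calls at 0.01 rest on that preset value. The genes named are the 12 with the largest rise and the 12 with the largest fall among those past the threshold, without overlap between groups, at a mean FPKM of at least 5 in the higher group and without predicted or clone names. Added to these are up to 4 members of each list with the largest change past the threshold, and 17 genes fixed in advance. Where 5 or fewer members went against the rest of a list, they are also named, and these exceptions were chosen after their values were seen. So were the Y-linked and X-linked genes, the genes and families at the start of the other observations, and the synthetase lists. The members of the cholesterol list that did not pass the test are not reported here. An exact two-sided permutation test of 2 against 2 libraries cannot give p below 0.333, so no gene has a permutation p under the threshold.

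Alternatives were pseudocounts of 0.1 and 0.01, no filter and a mean FPKM of at least 5, median-of-ratios scaling, quantile normalization, FPKM rescaled to equal library sums, eBayes without trend or with robust variance, a replicate block, each library left out in turn, a 2-fold minimum and the estimated correlation. Added after the data were seen were all 6 columns as 3 against 3, limma-voom on the recovered reads, a test without genes of chromosomes X and Y, and centring on the median gene. Genes with near-identical copies share reads, so the values of Ifna members, H2-Q6 and H2-Q7, Ifit3 and Ifit3b, Tgtp2, Hspa1a and Hspa1b, and Stfa1 and Cstdc5 are uncertain between copies.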

Results

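RNA sequencing compared BMDC given the calcium lipid nanoparticle NanoCa with Mock cells, labelled as given no treatment, and the series title sets it in work on interferon beta. The question is which transcripts differ between the NanoCa and Mock groups. Separate measurements came from 2 libraries per group, since the column of replicate 3 was in each group 1.0011 (NanoCa) or 1.001876 (Mock) times the mean of replicates 1 and 2. Library totals were 23991472 and 22793565 reads in NanoCa and 31131990 and 26975437 in Mock, and between 19676 and 20493 genes had a value per library. On log2(FPKM + 1), the libraries correlated across genes at r = 0.997 within each group and at 0.926 to 0.931 between groups (genes are not independent replicates). The first principal component separated the groups and held 95.9% of the variance.

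Transcripts linked to sex differed between the groups. Xist (ENSMUSG00000086503), the RNA that coats the inactive X chromosome of female cells, was at 33.4 ± 0.0940 FPKM in NanoCa (SD, n = 2; 14413 and 13639 reads) and had 1 read in each Mock library. The Y-linked genes Ddx3y, Uty, Eif2s3y and Kdm5d were found in all 4 libraries, and in NanoCa they stood at 40.4%, 39.0%, 33.6% and 29.4% of their Mock levels. Ddx3y, for example, was at 13.5 ± 0.863 FPKM in NanoCa and 33.5 ± 1.35 in Mock (log2 fold change -1.25, SE 0.057, adjusted p = 1.02e-05). The labels give female mice for every sample. Of their X-linked counterparts, which escape inactivation, Kdm5c and Kdm6a were at 102% and 99.3% of Mock (adjusted p = 0.674 and 0.888), while Eif2s3x and Ddx3x fell to 83.3% (log2 fold change -0.25, adjusted p = 0.00158) and 60.0% (-0.73, adjusted p = 2.25e-05). With median-of-ratios scaling Kdm5c (0.20, adjusted p = 0.00888) and Kdm6a (0.17, adjusted p = 0.0338) passed the test as higher, Eif2s3x did not pass it (-0.07, adjusted p = 0.211), and Ddx3x stayed lower (-0.54, adjusted p = 7.65e-05). Every difference below is a difference between libraries that also differ in these transcripts.

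**Figure D1:**
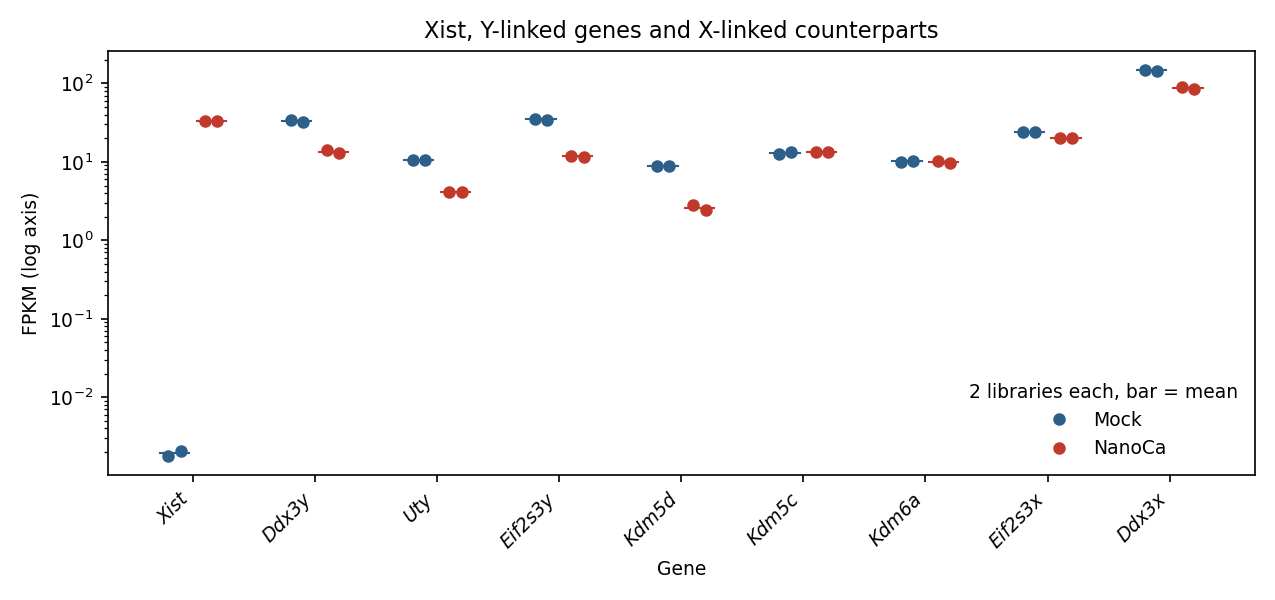
FPKM (log axis) of Xist, 4 Y-linked genes and their 4 X-linked counterparts in each of the 4 libraries, with Mock in blue, NanoCa in red and bars at the group means. Xist sits near 33.4 FPKM in NanoCa and at 1 read in each Mock library, and the Y-linked genes are present in both groups but lower in NanoCa.

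The largest rises in NanoCa were mostly of genes that interferon induces. Apart from Xist, they were Rsad2 (viperin, an antiviral enzyme; log2 fold change 5.02), Slfn4 (a schlafen protein of myeloid cells; 4.90), Ms4a4c (a membrane protein of monocytes; 4.90), Inhba (the activin A subunit; 4.75), Ifit3 (4.71), Isg15 (a ubiquitin-like modifier; 4.71), Irf7 (a transcription factor for interferon genes; 4.62), Cmpk2 (a mitochondrial nucleotide kinase; 4.59), Ifi205 (4.58), Oasl1 (4.49) and Ifit3b (4.47). The largest falls were of S100a9 (a calprotectin subunit of granulocytes; -5.47), the chemokine Ccl17 (-5.09), Wfdc21 (-4.12), the neutrophilic granule protein Ngp (-3.83), the lectin Mgl2 (-3.56), Cstdc5 and Stfa1 (stefin protease inhibitors; -3.53 and -3.02), Ifitm1 (-3.39), the lectins Cd209c (-3.21) and Asgr2 (-3.14), the cyclin Ccnb2 (-3.12) and the proliferation antigen Mki67 (-3.08). Isg15 (ENSMUSG00000035692) rose from 16.3 ± 3.82 FPKM in Mock to 446 ± 26.1 in NanoCa (SD, n = 2; SE of the log2 fold change 0.14, limma adjusted p = 2.38e-06). S100a9 (ENSMUSG00000056071) fell from 170 ± 78.2 to 2.78 ± 1.32 FPKM (SE 0.35, adjusted p = 3.86e-05), with the Mock libraries at 115 and 225. In all, 2409 genes were higher and 5520 lower in NanoCa, and 3187 of 11116 did not pass the test. Among the genes past the test, 561 were higher and 643 lower by at least 2-fold, a balance that turned with median-of-ratios scaling (705 and 464) and quantile normalization (646 and 469) and widened with a pseudocount of 0.01 (688 and 995) and limma-voom (687 and 994). The groups did not overlap for 86.3% of genes, where chance gives 33.3%. The median log2 fold change of all genes tested was -0.17. With median-of-ratios scaling, which shifts it by 0.17, 3717 genes were higher and 3620 lower, and with quantile normalization, a shift of 0.13, 3307 and 4040. Group medians are therefore also given relative to that of all genes. Without genes of chromosomes X and Y, 2357 genes were higher and 5320 lower.

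Ifnb1 (ENSMUSG00000048806), which encodes interferon beta, was higher in NanoCa, at 4.56 and 3.69 FPKM against 0.0857 and 0.0494 in Mock. These values rest on 82 and 63 reads against 2 and 1, a ratio of read rates of 60.0 (exact 95% interval 20.1 to 294, counting error only). The log2 fold change was 2.26 (SE 0.11, adjusted p = 1.28e-05). The 14 Ifna family members together had 12 reads in NanoCa and 1 in Mock, a ratio of 14.9 (2.21 to 637). Ifna4, an early alpha interferon, had 3 and 2 reads in NanoCa and 0 in Mock, and the exact 95% interval of this ratio starts at 1.14. Ifnl2 and Ifnl3, the interferon lambda genes, had 0 reads in every library.

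All 49 tested interferon-stimulated genes rose, 47 of them by at least 2-fold. Rsad2 went from 17.4 ± 2.49 to 595 ± 6.19 FPKM (SD, n = 2; adjusted p = 8.28e-07), Ifit3 from 26.5 ± 5.27 to 716 ± 54.5 (adjusted p = 1.86e-06) and Irf7 from 14.1 ± 3.04 to 366 ± 18.1 (adjusted p = 2.04e-06). The list's median log2 fold change was 2.37, or 2.54 above that of all genes (camera adjusted p = 2.19e-31; adjusted p = 0.302 with an estimated correlation). Counts adjusted over the list alone were the same for this list and every other, except for 2 lists where they are given. Among guanylate-binding proteins, immunity-related GTPases (both defend against intracellular pathogens) and Cxcr3 ligands, 16 of 17 rose, with a median of 1.97, or 2.14 relative to all genes (camera adjusted p = 1.06e-11; adjusted p = 0.323 with an estimated correlation). Examples are Tgtp2 (4.12), Iigp1 (3.07), Igtp (2.62) and Cxcl10, a T cell attractant, which went from 12.2 ± 1.97 to 152 ± 2.67 FPKM (3.54, SE 0.095). Gbp8 fell (-0.28).

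Of 21 nucleic acid sensing genes, 13 rose, 4 fell and 4 did not pass the test. The endosomal receptor Tlr3 (1.63), the transporter Slc15a3 (1.22) and the ubiquitin ligase Trim25 (1.05) rose. Sting1, the adaptor for cyclic dinucleotides, fell from 33.9 ± 0.520 to 14.6 ± 0.238 FPKM (-1.17, SE 0.041, adjusted p = 3.93e-06), as did Enpp1 (-0.73), Mavs (-0.53) and Tlr8 (-0.49). The list's median was 0.23, or 0.40 above that of all genes (camera adjusted p = 0.000449; adjusted p = 0.302 with an estimated correlation).

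**Figure D2:**
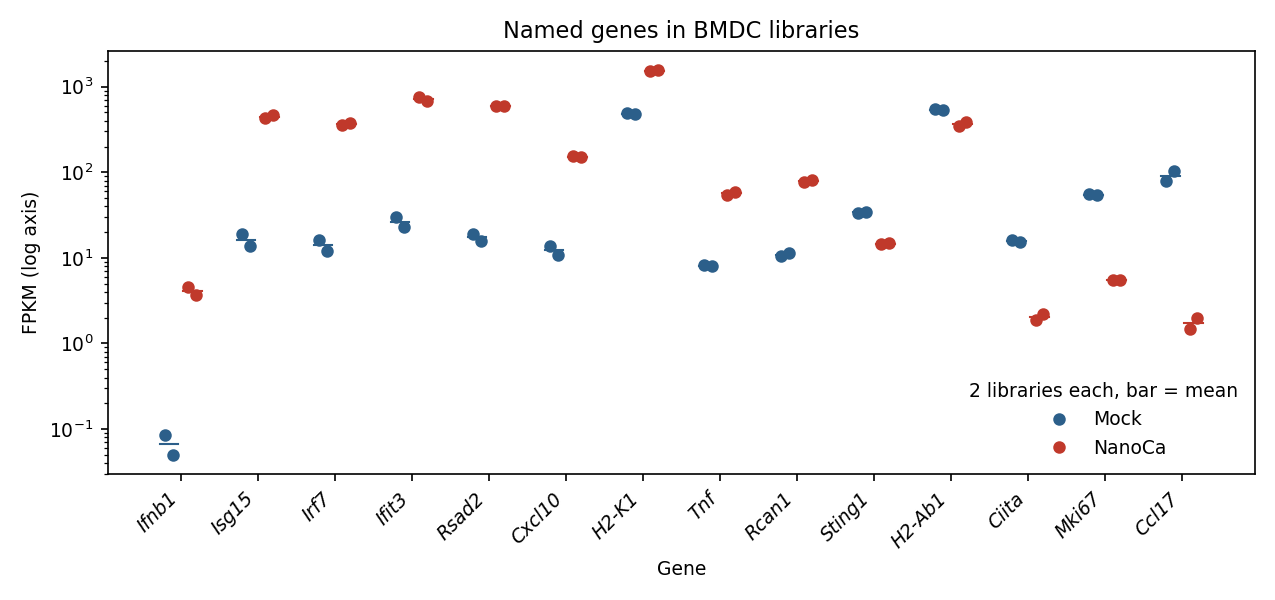
FPKM (log axis) of genes named in the text in each of the 4 libraries, with Mock in blue, NanoCa in red and bars at the group means. Isg15 lies near 446 FPKM in NanoCa and 16.3 in Mock, while Sting1, H2-Ab1, Ciita, Mki67 and Ccl17 are lower in NanoCa.

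Inflammatory cytokine, chemokine and NF-kB feedback genes rose in 27 of 31 cases and fell in 3 (27 and 2 with median-of-ratios scaling). Cxcl2, a neutrophil attractant, rose by a log2 fold change of 4.27, Ccl5 by 3.12 and Nos2, the inducible nitric oxide synthase, by 3.01. Tnf went from 8.08 ± 0.133 to 56.8 ± 2.85 FPKM (2.67, SE 0.049, adjusted p = 8.68e-07). Il1b (0.64, adjusted p = 5.46e-05) and Il6 (0.52, adjusted p = 0.0052) rose less, and Il6 was low in both groups, at 1.79 ± 0.253 and 0.942 ± 0.138 FPKM. Ccl17, Tnfaip2 (-0.32) and Ccl22 (-0.29) fell, and Lcn2 was at -0.24 (adjusted p = 0.232). The list's median was 1.41, or 1.59 above that of all genes (camera adjusted p = 2.61e-14; adjusted p = 0.302 with an estimated correlation).

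Dendritic cell maturation genes rose in 17 of 23 cases and fell in 3 (20 and 2 with median-of-ratios scaling). Their median was 0.84, or 1.01 relative to all genes (camera adjusted p = 3.45e-07; adjusted p = 0.302 with an estimated correlation). Cd200 (2.38), Marcksl1 (1.78) and the costimulatory genes Cd40 (1.46) and Cd86 (1.19) rose. Cd86 went from 18.1 ± 0.162 to 42.5 ± 1.51 FPKM (adjusted p = 4.29e-06), while Cd40 stayed low at 2.78 ± 0.374 FPKM in NanoCa. Pdcd1lg2, which encodes the checkpoint ligand PD-L2, fell (-2.02), as did Socs2 (-1.26) and Ccl22. Cd80 was at 6.82 ± 0.496 FPKM in NanoCa and 6.38 ± 0.224 in Mock (0.08, adjusted p = 0.298), and with median-of-ratios scaling it passed the test (0.25, adjusted p = 0.0138; range over all settings 0.0103 to 0.841).

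The 2 arms of antigen presentation moved in opposite directions. All 23 MHC class I genes rose, with a median of 1.19, or 1.36 above that of all genes (camera adjusted p = 3.47e-16; adjusted p = 0.302 with an estimated correlation). H2-K1, a classical class I heavy chain, went from 485 ± 10.8 to 1547 ± 29.2 FPKM (1.67, SE 0.044, adjusted p = 1.74e-06), and H2-Q6 (3.84), H2-Q7 (3.81), H2-Q4 (1.94) and H2-T22 (1.85) rose too. Of 13 MHC class II genes, 12 fell, with a median of -0.91, or -0.74 relative to all genes (camera adjusted p = 0.00251; adjusted p = 0.375 with an estimated correlation). Ciita, the master transactivator of class II genes, went from 15.7 ± 0.366 to 2.05 ± 0.224 FPKM (-2.46, SE 0.069, adjusted p = 2.08e-06). The peptide exchange factors H2-DMb2 (-1.84), H2-DMa (-1.48) and H2-DMb1 (-1.10) fell, and H2-Ab1 fell less, from 539 ± 4.88 to 367 ± 22.2 FPKM (-0.55, adjusted p = 0.000182). The protease gene Ctss rose (0.58).

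Genes of the unfolded protein and integrated stress responses rose in 18 of 26 cases and fell in 6 (20 and 3 with median-of-ratios scaling), with a median of 0.44, or 0.62 relative to all genes (camera adjusted p = 1.1e-06; adjusted p = 0.302 with an estimated correlation). Asparagine synthetase Asns (3.07), the pseudokinase Trib3 (2.97), Ddit3 (CHOP, a transcription factor of endoplasmic reticulum stress; 2.53) and the phosphatase subunit Ppp1r15a (1.98) led the rise. Ddit3 went from 9.62 ± 0.480 to 60.2 ± 2.08 FPKM (SE 0.051, adjusted p = 1.03e-06). NRF2 response genes rose in 13 of 24 cases and fell in 6 (15 and 2 with median-of-ratios scaling, 11 and 8 with quantile normalization), with a median of 0.27, or 0.44 relative to all genes (camera adjusted p = 0.00219; adjusted p = 0.375 with an estimated correlation; adjusted p = 0.0766 with quantile normalization). Sqstm1, the autophagy receptor p62, rose (2.12), as did heme oxygenase Hmox1 (1.56) and Srxn1 (1.42), while Gstm1 fell (-1.36). Of 15 heat shock and metallothionein genes, 7 were higher and 3 lower (11 and 2 with median-of-ratios scaling), with a median of 0.10, or 0.27 relative to all genes (camera adjusted p = 0.0113; adjusted p = 0.302 with an estimated correlation). Hspa1b (1.40) and Hspa1a (1.30) rose, Mt1 (-1.22), Mt2 (-1.10) and Hspe1 (-0.18) fell, and the call was lost with a mean FPKM of at least 5 (0.107) and with quantile normalization (0.0708). Immediate early genes rose in 17 of 23 cases, with a median of 0.80, or 0.97 relative to all genes (camera adjusted p = 6.35e-07; adjusted p = 0.302 with an estimated correlation). The phosphatases Dusp1 (3.08) and Dusp4 (2.84) and the transcription factors Maff (2.17) and Fos (1.63) rose, and Klf4 (-0.99), Klf2 (-0.58), Fosl2 (-0.49) and Btg2 (-0.40) fell.

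Among calcium handling and calcineurin-NFAT genes, 7 of 42 rose and 25 fell (26 fell adjusted over the list alone), with a median of -0.22, or -0.05 relative to all genes. The list was not called (camera adjusted p = 0.317), and with median-of-ratios scaling 11 members were higher and 15 lower. Rcan1, the calcineurin regulator that NFAT induces, was the exception in size, at 78.4 ± 3.20 FPKM in NanoCa and 10.9 ± 0.679 in Mock (2.74, SE 0.056, adjusted p = 1.03e-06). The calcium pump Atp2a3 (-1.29), the kinase Camk1 (-0.85) and Rcan3 (-0.82) fell.

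Inflammasome and lytic cell death genes rose in 12 of 20 cases and fell in 6, with a median of 0.47, or 0.65 relative to all genes (camera adjusted p = 0.00219; adjusted p = 0.302 with an estimated correlation). Il18bp, the interleukin 18 decoy, rose (1.92), as did Casp4 (1.26), Mefv (1.23) and Mlkl, the effector of necroptosis (0.93). For p53 and apoptosis genes, 7 of 22 rose and 11 fell, a balance that turned with median-of-ratios scaling (11 higher and 8 lower; 10 and 10 with quantile normalization), and the list was not called. Its median was -0.08, or 0.09 relative to all genes, and its mean 0.05, camera pointed up (adjusted p = 0.376) and fry pointed down. Mdm2 (1.57), Cdkn1a (1.14) and Bcl2l1 (1.09) rose and Trp53inp1 fell (-1.02). Lysosome and autophagy genes rose in 19 of 35 cases and fell in 8 (20 and 8 adjusted over the list alone, 24 and 5 with median-of-ratios scaling, 14 and 9 with quantile normalization), with a median of 0.22, or 0.39 relative to all genes (camera adjusted p = 0.000176; adjusted p = 0.302 with an estimated correlation; adjusted p = 0.0766 with quantile normalization). The protease Ctsl (1.23), the cholesterol carrier Npc2 (1.20), Gla (0.87) and Grn (0.84) rose.

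Glycolysis and hypoxia response genes rose together, in 23 of 23 cases, with a median of 1.27, or 1.45 above that of all genes (camera adjusted p = 3.87e-17; adjusted p = 0.302 with an estimated correlation). Egln3, an oxygen-sensing prolyl hydroxylase, went from 1.36 ± 0.00899 to 21.1 ± 0.135 FPKM (3.23, SE 0.052, adjusted p = 6.82e-07), and Ankrd37 (2.65), the angiogenic factor Vegfa (2.29) and the mitophagy receptor Bnip3 (2.04) rose. Cholesterol synthesis and uptake genes fell in 22 of 24 cases, with a median of -0.78, or -0.61 relative to all genes (camera adjusted p = 1.7e-05; adjusted p = 0.302 with an estimated correlation). The sterol carrier Stard4 (-1.47) and the enzymes Mvd (-1.34), Acat2 (-1.29) and Nsdhl (-1.12) fell. LXR target and lipid storage genes were divided, with 9 of 21 higher and 8 lower and no call (camera adjusted p = 0.173). Their median was -0.06, or 0.12 relative to all genes, their mean 0.19 and camera pointed up. Hilpda (2.90), Apoe (2.05) and Pltp (1.71) rose and the desaturase Scd1 fell (-2.17).

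Oxidative phosphorylation subunits fell in 31 of 49 cases by small amounts, with a median of -0.26, or -0.09 relative to all genes (camera adjusted p = 0.0383; adjusted p = 0.504 with an estimated correlation). Uqcrh (-0.82), Uqcrfs1 (-0.75), Ndufa4 (-0.67) and Ndufs1 (-0.62) fell the most, and Cycs (0.48) and Uqcrq (0.24) rose. The call was lost with median-of-ratios scaling (adjusted p = 0.25; 10 higher and 20 lower), without NanoCa replicate 1 (0.104) and without Mock replicate 2 (0.0526). Of 13 mitochondrially encoded transcripts, 11 fell, with a median of -0.68, or -0.51 relative to all genes, and no call (camera adjusted p = 0.141; adjusted p = 0.0254 with median-of-ratios scaling). The respiratory chain transcripts mt-Cytb (-1.06), mt-Nd1 (-1.06), mt-Co3 (-0.86) and mt-Nd2 (-0.78) fell, and the ribosomal RNAs mt-Rnr1 (0.69) and mt-Rnr2 (0.53) rose. The value of mt-Co3 rests on few reads, 24 and 37 in NanoCa and 100 and 75 in Mock. It was at 1.67 FPKM in NanoCa and 3.82 in Mock, where mt-Cytb was at 1949 and 4069.

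Cell cycle genes fell in 37 of 39 cases, 32 of them by at least 2-fold, with a median of -2.13, or -1.96 relative to all genes (camera adjusted p = 2.33e-10; adjusted p = 0.302 with an estimated correlation). Mki67 went from 54.6 ± 0.754 to 5.56 ± 0.0272 FPKM (SE 0.041, adjusted p = 6.82e-07), and the mitotic cyclins Ccnb2 (-3.12), Ccnb1 (-2.99) and Ccna2 (-2.95) fell alongside. The replication clamp Pcna rose (0.48), and Cdt1 was at 0.12 (adjusted p = 0.183). Granulocyte precursor markers were lower in the same libraries.

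**Figure D3:**
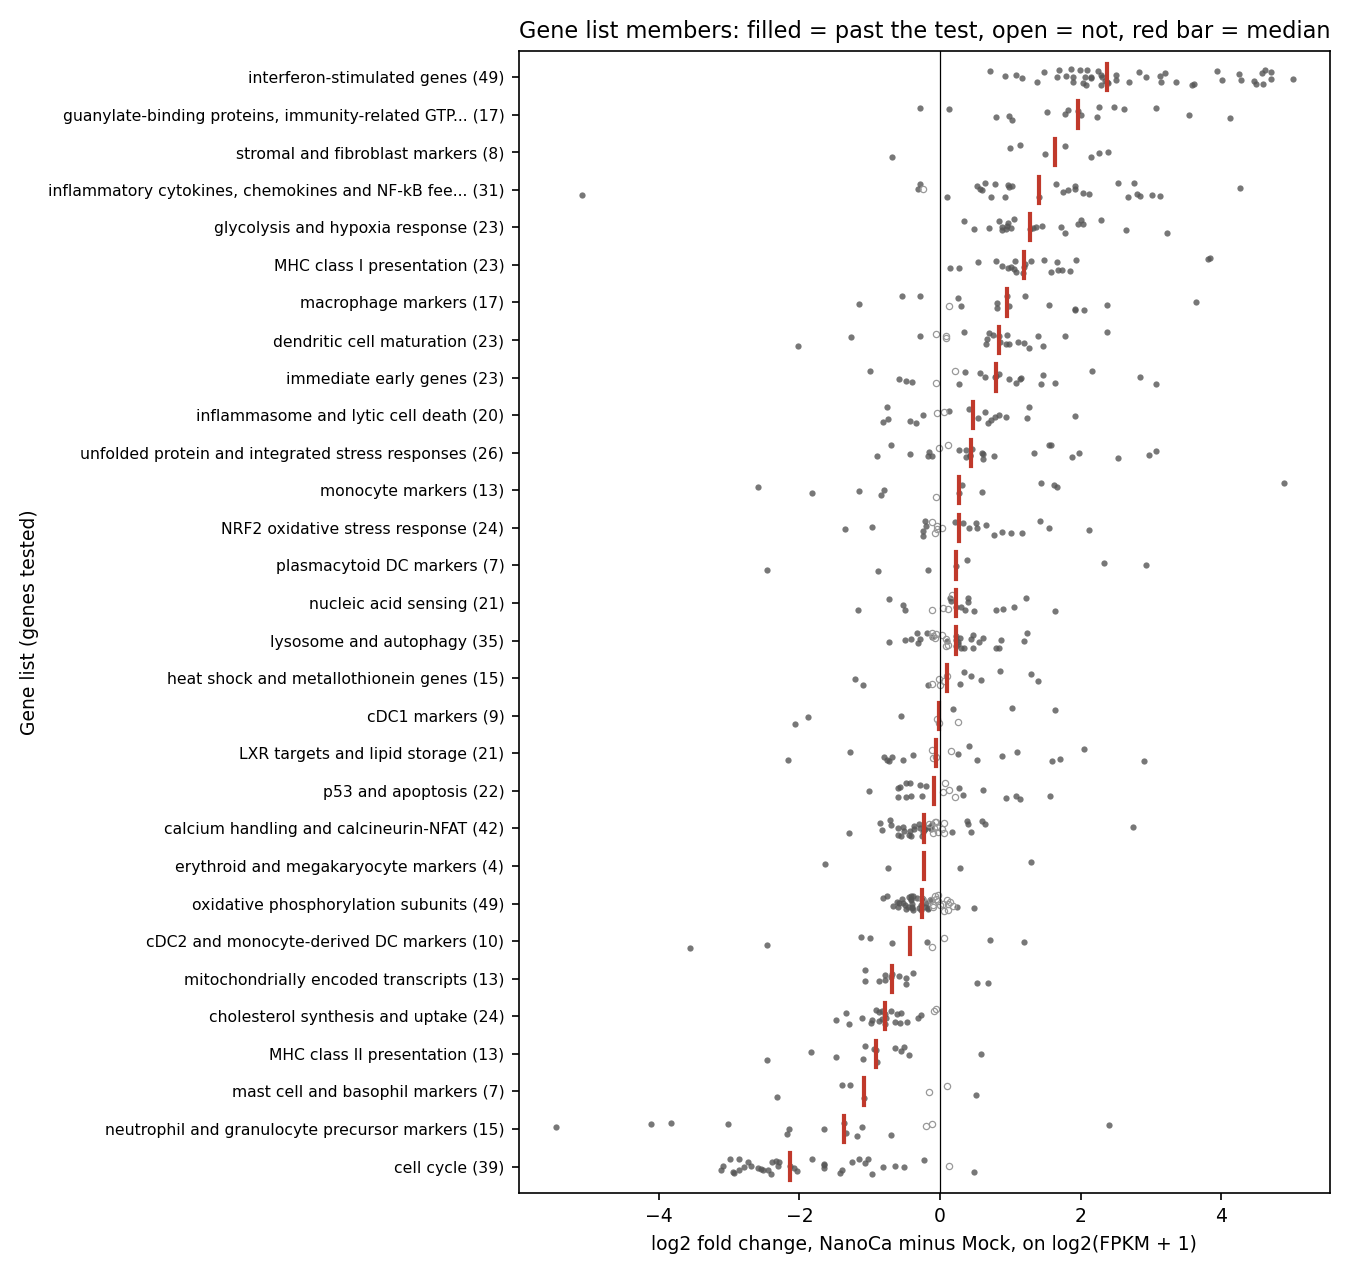
Log2 fold change (NanoCa minus Mock, on log2(FPKM + 1)) of each tested member of the gene lists with at least 3 tested members, 1 point per gene, filled where the gene passed the test and open where it did not, with a red bar at each list's median. Of these lists, interferon-stimulated genes have the highest median, 2.37, and cell cycle genes the lowest, -2.13.

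Markers of other cell types also differed. Neutrophil and granulocyte precursor markers fell in 12 of 15 cases, with a median of -1.36, or -1.19 relative to all genes (camera adjusted p = 0.0199; adjusted p = 0.515 with an estimated correlation; adjusted p = 0.0906 with a mean FPKM of at least 5). S100a9, Wfdc21, Ngp and Stfa1 led the fall, the gelatinase Mmp9 rose (2.41), and Cebpe (-0.21, adjusted p = 0.102) and Padi4 (-0.12, adjusted p = 0.284) did not pass the test. Macrophage markers rose in 13 of 17 cases and fell in 3 (14 and 2 with median-of-ratios scaling). Their median was 0.95, or 1.12 relative to all genes (camera adjusted p = 9.95e-07; adjusted p = 0.302 with an estimated correlation). The scavenger receptor Marco (3.64), Folr2 (2.37), the apolipoprotein Apoe and the Fc receptor Fcgr1 (1.92) rose, while Mrc1 (-1.16), Gas6 (-0.54) and Mertk (-0.28) fell. Stromal and fibroblast markers rose in 7 of 8 cases, with a median of 1.63, or 1.81 relative to all genes (camera adjusted p = 1.89e-05; adjusted p = 0.302 with an estimated correlation). Sparc (2.39) and the collagens Col1a2 (2.27), Col1a1 (2.14) and Col3a1 (1.78) rose from levels of 0.832 to 5.17 FPKM in Mock to 5.30 to 31.3 FPKM in NanoCa, and the endothelial gene Pecam1 fell (-0.68).

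The dendritic cell subset lists had no call. Of 9 cDC1 markers, 3 rose and 3 fell (5 and 3 with median-of-ratios scaling; camera adjusted p = 0.376), with Tlr3 and Rab7b (1.02) higher and Naaa (-2.06) and the receptor Clec9a (-1.87) lower. Their median was -0.01, or 0.16 relative to all genes, and their mean -0.16, with camera pointing up and fry down. Of 10 cDC2 and monocyte-derived DC markers, 2 rose and 6 fell (camera adjusted p = 0.376). Mgl2, the lectin Clec10a (-2.46) and Irf4 (-1.13), a transcription factor of this subset, fell, and Tnip3 rose (1.19). Of 7 plasmacytoid DC markers, 4 rose and 3 fell (camera adjusted p = 0.208), with the interferon-inducible tetherin gene Bst2 (2.93) and Cox6a2 (2.34) higher and Klk1b27 (-0.89) lower. Of 13 monocyte markers, 7 rose and 5 fell (camera adjusted p = 0.224), the median being 0.28, or 0.45 relative to all genes, camera pointing up and fry down. The chemokine receptor Ccr2 went from 427 ± 13.5 to 69.6 ± 1.47 FPKM (-2.60, adjusted p = 6.82e-07), Vcan fell (-1.83), and Ms4a4c and Ms4a6c (1.66) rose.

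Of 7 mast cell and basophil markers, 4 fell and 1, Il3ra (0.50), rose (camera adjusted p = 0.597). The protease genes Cpa3 (-2.31), Prss34 (-1.40) and Mcpt8 (-1.08) and the receptor Kit (-1.28) fell. Erythroid and megakaryocyte markers were divided, with 2 of 4 higher and 2 lower, a median of -0.23, or -0.05 relative to all genes, and no call (camera adjusted p = 0.651, pointing up). Ppbp (-1.63) and Itga2b (-0.74) fell, carbonic anhydrase Car2 rose (1.29), and Pf4 rose by 0.29 (adjusted p = 0.0164), a call lost without the filter (0.0839), with quantile normalization (0.071) and without NanoCa replicate 2 (0.0721; range over all settings 0.000746 to 0.0839). The B cell list had 1 tested member, Ighm, the IgM heavy chain, which fell (-2.90). No T or NK cell marker reached the filter, and the highest of them, Cd4, was at 0.710 ± 0.0938 FPKM in NanoCa and 0.446 ± 0.0567 in Mock.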

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

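All 6 columns as 3 against 3, limma-voom, the test without genes of chromosomes X and Y and the centring on the median gene were chosen after seeing the data. No called gene (0) passed the test in the opposite direction under the other scalings, filters, variance models or tests. A change of sign without passing the test was not counted. Of 7929 calls, 6029 kept call and direction with median-of-ratios scaling, 6217 with quantile normalization and 5979 with centring on the median gene. The counts of genes higher and lower moved with median-of-ratios scaling (3717 and 3620), centring (3718 and 3570) and a 2-fold minimum (561 and 643), the last by its own construction. At 2-fold, median-of-ratios scaling gave 705 and 464, quantile normalization 646 and 469, centring 719 and 444, a pseudocount of 0.1 676 and 951, and a pseudocount of 0.01 688 and 995. They were 2139 to 2271 and 4948 to 5125 with 1 library left out, where the lone library is assumed to vary like the other group. All 6 columns gave 2969 and 6464, limma-voom 2487 and 5609, and a replicate block 2538 and 5691. The block changed no call of a list. Same-numbered libraries deviated together at r = 0.133 across genes, over 2 pairs that the labels do not tie. This cannot settle whether the numbers pair the samples, and the main test used no block. Leaving out replicate 3 equals the values reported, which do not use it. Because the deposited values are FPKM, limma-voom on the recovered reads was the only model of counts run, and only as an alternative.

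The next count covers the 137 tested genes named by the rule fixed in advance. Of these, 135 kept their side of the threshold and direction under every alternative that tested them, and the exceptions were Cd80 and Pf4. Other genes, named after their values were seen, are not in it. Among those, Kdm5c, Kdm6a and Eif2s3x changed sides of the threshold with median-of-ratios scaling. Of 20 lists called, 15 kept the call under every alternative but 1. With an estimated correlation 0 of 20 kept it, at adjusted p = 0.302 for 15 lists, 0.375 for class II and NRF2, 0.323 for GTPases, 0.504 for oxidative phosphorylation and 0.515 for granulocyte markers. With 2 libraries per group this setting has little power, and the 15 lists include interferon-stimulated genes, of which 49 of 49 rose. It therefore does not decide whether correlation between genes accounts for the calls. Without the filter, mitochondrially encoded transcripts passed (0.0212) and erythroid markers turned down (0.661). At a mean FPKM of at least 5, p53 genes turned down (0.956), and heat shock genes (0.107) and granulocyte markers (0.0906) lost the call, with fewer genes tested. With median-of-ratios scaling oxidative phosphorylation lost it (0.25), mitochondrial transcripts passed (0.0254) and erythroid markers turned down (0.968). With quantile normalization NRF2 and lysosome genes (0.0766 each) and heat shock genes (0.0708) lost it, mitochondrial transcripts passed (0.028) and erythroid markers turned down (0.963). Without a trend oxidative phosphorylation was at 0.0879, and 0.0132 to 0.104 with 1 library left out. With all 6 columns it and granulocyte markers were each at 0.0558. Apart from the filters, the cause was not tested. Depth limits low genes: 1 read per kilobase is worth up to 0.0439 FPKM.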

Other observations

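The genes and families of the next paragraph were chosen after seeing the data, as were the tests of a mix of animals, of a mislabelled library, of scaling as the source of the many lower calls, of transcripts per cell, of fewer granulocyte precursors and of the splits. The tests of X chromosome silencing, of scaling for the granulocyte markers and of the synthetases had their bounds set before their results were seen. The members of the synthetase lists were themselves chosen after the data were seen.

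Some single genes outside the fixed lists moved strongly. Arg1, which encodes the arginine-degrading enzyme arginase 1, went from 3.62 ± 1.52 FPKM in Mock to 91.1 ± 0.824 in NanoCa (SD, n = 2; log2 fold change 4.36, limma adjusted p = 1.04e-05), and the neuropeptide gene Npy from 19.4 ± 1.19 to 325 ± 13.2 (4.00, adjusted p = 6.82e-07). Gem, a small GTPase that restrains calcium channels (3.62), the collagen hydroxylase P4ha2 (3.49), Cd72 (3.39) and Rgs1, a regulator of G protein signalling (3.37), rose too. Lyz2, the myeloid lysozyme and one of the most abundant transcripts, fell from 23675 ± 187.4 to 4945 ± 97.8 FPKM (-2.26, adjusted p = 2.25e-06). Within the fixed macrophage list, Cd14 (1.92), Cd68 (0.98) and Adgre1 (0.95) rose, and the actin gene Actb was at 0.12 (adjusted p = 0.0643). Ribosomal protein genes fell in 69 of 81 cases and rose in 1, with a median of -0.40, where that of all genes was -0.17 (camera adjusted p = 4.5e-06; adjusted p = 0.585 with an estimated correlation). With median-of-ratios scaling 47 were lower and 3 higher. Proteasome subunits rose in 28 of 37 cases and fell in 2, with a median of 0.25 (camera adjusted p = 3.12e-09; adjusted p = 0.0934 with an estimated correlation). With median-of-ratios scaling 33 were higher and 0 lower. They include Psmb8, Psmb9 and Psmb10, which are also in the class I list. Vacuolar ATPase subunits rose in 8 of 17 cases and fell in 5, with a median of 0.11 (camera adjusted p = 0.0209; adjusted p = 0.205 with an estimated correlation). With median-of-ratios scaling 11 were higher and 3 lower. Part of them, such as Atp6v0d1 and Atp6v1a, are also in the lysosome list.

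Xist was present in NanoCa and nearly absent in Mock, and Y-linked transcripts were lower in NanoCa, although the labels give female mice throughout. The Y-linked genes had a median NanoCa to Mock ratio of 0.363 with Xist at 1 read per Mock library, which is consistent with male cells in Mock and a mix of male and female cells in NanoCa, while the 4 X-linked counterparts that escape inactivation went different ways (60.0% to 102% of Mock) and decide nothing here. Xist switched on in male cells would lower X-linked genes. The 333 tested X-linked genes lay 0.10 below the 10746 autosomal ones (difference of medians -0.0964, bootstrap 95% interval -0.147 to -0.0602). The interval treats genes as independent and leaves out the spread between libraries. So small a fall argues against silencing that had reached the X-linked transcripts of most cells. A recent or partial onset cannot be excluded, since the time of exposure is not given. A single wrong label is argued against by the ratio between the 2 libraries of a group, at most 1.14 over the Y-linked genes in both groups and Xist in NanoCa. The groups may thus differ in animals as well as in treatment, and no library here separates these, so any gene's difference could carry a part from the animals.

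More than 2 genes were lower for each gene that was higher. With median-of-ratios scaling 50.7% of calls were higher, against 30.4% as deposited, but that scaling places the median gene near 0 and so sets the balance by its own construction. An effect of scaling to the total reads and a fall of most transcripts per cell cannot be told apart, because 0 libraries carry an external standard or an RNA yield per cell.

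Granulocyte precursor markers were lower in NanoCa, in 12 of 15 cases. Scaling to total reads is argued against by the size of the falls. Median-of-ratios scaling shifts the median gene by 0.17, while the 12 lower members were at log2 fold changes of -0.70 or below. With that scaling 80% of tested members were lower as well, a share that a shift of this size could hardly have changed. The members did not move alike: S100a8, the partner of S100a9, fell by 1.18 on the log2 scale where S100a9 fell by 5.47, Mmp9 rose, and Mmp8 (168 and 165 FPKM in NanoCa, 755 and 730 in Mock) differed little between the Mock libraries. Of the 12 lower members, 10 were higher in Mock replicate 2 than in Mock replicate 1. Fewer such cells in the NanoCa cultures and a change of these genes within cells both stay open, since no library here counts the cells.

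Asns, Trib3 and Ddit3 are targets of the transcription factor ATF4, which led to the hypothesis that ATF4 activity rose. Its known targets include part of the cytosolic aminoacyl-tRNA synthetases, so these should exceed the other synthetases. Of 11 target synthetases 10 rose, led by Aars (1.10) and Cars (0.94), and of the 8 others 2 rose and 4 fell, which became 4 higher and 2 lower with median-of-ratios scaling, where 10 target synthetases were higher and 0 lower. The medians differed by 0.356 (permutation p = 0.0366, genes not being independent replicates), between the 0.25 and 0.5 set as bounds before the test, which leaves the hypothesis undecided. The lists were chosen after the data were seen, so this p-value is not that of a comparison fixed in advance. Wars, another cytosolic synthetase gene, rose (0.50) and was in neither list.

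The 4 libraries can be split into 2 pairs in 3 ways, and 1 of them, the real one, gave as many genes as the real 7929. The highest of the other splits gave 0 genes with limma (11 and 10 at an unadjusted p under 0.05). Those splits mix NanoCa and Mock libraries within each pair, so the difference between the groups counts there as spread. Few calls in them were thus fixed in advance and decide nothing. With 3 splits the share cannot be under 0.05.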
